A study of Homo sapiens with 3 samples.

How the data were processed

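Total RNA of A549 cells transfected with a control vector or a SpiB expression vector was measured on 3 two-colour Agilent oligonucleotide arrays of 1 slide, each with 1 control culture in Cy3 and 1 SpiB culture in Cy5. Per the labels' protocols, RNA was polyadenylated, copied into double-stranded DNA from oligo-dT primers, turned into antisense cDNA through reverse transcription of cRNA, and labelled with Cy3 or Cy5 by Klenow enzyme. The 3 control and 3 SpiB cultures were grown and harvested independently, per the series' design text. The arrays formed a single comparison, and the array paired a control with a SpiB culture. All 3 lay on 1 slide, so the slide was no batch.

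The deposited scanner files hold, per the file headers, the output of Agilent Feature Extraction 11.5.1.1 (version 11 in the submitters' processing notes) for an array design based on genome build hg19. The authors deposited spot intensities as medians with a median local background for each channel, flags for outliers, saturation and signal above background, and the log10 ratio of the processed, background-corrected and dye-normalized signals of Cy5 over Cy3. The deposited series table holds log2 values. These equalled the log2 ratio of the processed Cy5 over Cy3 signals within 0.001 for 99.25%, 98.97% and 98.98% of 50739 rows on replicates 1, 2 and 3, so its scale and direction are known, and no centring on genes was found. Its column medians were 0.02, 0.07 and 0.08. It was used as an alternative.

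Mean spot signals had been planned, and median spot signals were used because the files hold these. The background was corrected with normexp at an offset of 50, the log ratios were normalized within each array by loess with control and outlier spots at weight 0, outlier spots (585, 825 and 956 on replicates 1, 2 and 3) were left out, and spots of a probe were averaged. A probe was tested when it was well above background in at least 1 channel on 2 of the 3 arrays. Probes were named through their RefSeq accession, without versions, in a gene table of assembly GRCh38.p14. Of 50599 probes, 28174 matched 1 gene symbol and 22425 were unnamed here, which gave 20503 genes on the array and 17074 tested. No coordinates are given because the design's build differs from that of the table. Of the fixed list members, TJP3, FCGR1A, LYZ, AIF1, IFI27, NFKB2, AKR1C2, ALDOA and MUC5AC matched no probe and were not analysed here.

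The mean log2 ratio of each tested probe was compared with 0 using limma 3.58.1 (lmFit with an intercept, eBayes over all tested probes) in R 4.3.3, two-sided. A gene was represented by its tested probe with the highest mean intensity, and p was adjusted over genes by the Benjamini-Hochberg method with a threshold of 0.05. Of 1128 other tested probes of called genes, 990 had the same sign as the named probe and 11 passed the threshold with the opposite sign. Errors are standard deviations over the 3 arrays. For a gene above background in 1 channel only, the bound uses the levels of each channel after loess and Aquantile normalization.

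Genes were named by a rule fixed before the data were examined. It took SPIB, SPI1, SPIC and CLDN2, the 10 highest and 10 lowest mean ratios among called genes with the same sign on all arrays and both channels above background on all of them, up to 5 genes per direction with 1 channel above background on all arrays and the other on none, and up to 2 called members per direction of each list. Other genes are named where the text says so, and PTPRC, FCER1G and MPEG1 were chosen after their values were seen. Some genes that the rule takes are not reported here. The 23 lists were fixed at the same time: myeloid, B cell lineage, plasmacytoid dendritic and M cell, fibroblast and endothelial, NF-kB cytokine, interferon-stimulated, matrix proteolysis, unfolded protein response, ribosomal protein, tight junction, integrin and basement membrane, epithelial adhesion and keratin, mesenchymal transition, TGF-beta response, lung epithelial lineage, ETS family, cell cycle, p53 target, apoptosis regulator, NRF2 target, hypoxia and glycolysis, sterol and fatty acid synthesis, and autophagy and lysosome. They were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 23 lists. Camera with an estimated correlation and fry were run beside it.

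The pipeline was tested on simulated data of the same 17074 genes with the spread of these arrays. It called 78.8% of genes raised by a log2 ratio of 2, 48.5% of those raised by 1 and 0% of those raised by 0.5; the shares were 88.2%, 41.2% and 0% for decreases of those sizes. None of 86 calls was an unchanged gene. Only 220 genes were changed in the simulation, a far smaller share than the 19.3% called in the data, which makes the adjusted threshold stricter. The shares are therefore not the detection rates of the real comparison, where VIM passed at 0.35. A small change can still be missed. The simulated noise was independent between probes and held no dye effect of single probes, so the absence of false calls does not cover such errors. The alternatives were median centring in place of loess, Aquantile normalization, no background correction, an offset of 16, the scanner's log ratio, the authors' value table, 2 other filters on dim probes, outlier spots kept, a trended robust prior, separate channels without the pairing of cultures on an array, the mean of a gene's probes, a minimum change of 2-fold, each replicate left out, and, chosen after seeing the data, ratios scaled to the same spread on every array.

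The processing can affect the values in several ways. Loess removes an intensity-dependent dye effect and assumes that changes are balanced at each intensity. Dye effects of single probes stay, since no array had the dyes swapped. The offset shrinks the ratios of dim probes.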

Results

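Gene expression was compared between A549 cells transfected with a SpiB expression vector and A549 cells transfected with a control vector. A549 is an established line of human lung adenocarcinoma cells. SpiB, the product of SPIB, is a transcription factor of the ETS family, closely related to PU.1 (the product of SPI1) and best known from B cells and plasmacytoid dendritic cells. Total RNA of 3 control and 3 SpiB cultures, grown and harvested independently, was hybridised to 3 two-colour oligonucleotide arrays. Each array held 1 control culture labelled with Cy3 and 1 SpiB culture labelled with Cy5, so that the log2 ratio of Cy5 over Cy3 gave SpiB over control in 3 culture pairs, called replicates 1, 2 and 3. The dyes were not swapped on any array, and a gene-specific dye effect would therefore enter every ratio below. The number of arrays, 3, limits the precision of all values.

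Of 50599 probes other than controls, 69.3%, 68.4% and 70.3% were well above background in the control channel of replicates 1, 2 and 3, and 68.9%, 64.6% and 66.6% in the SpiB channel. Median signals were 340, 312 and 322 in the control channel over backgrounds of 23, 22 and 22.5, and 511, 610.5 and 519 in the SpiB channel over backgrounds of 39, 42 and 41. No spot was saturated. Across the 35284 probes that were tested, the log2 ratios of replicates 1 and 2 correlated with r = 0.835, those of replicates 1 and 3 with r = 0.723, and those of replicates 2 and 3 with r = 0.641; these are correlations across probes, which are not independent replicates. The ratios of replicate 3 were less spread, with a standard deviation of 0.40 against 0.50 and 0.53. The log ratios of the spike-in transcripts rose with their expected log ratios at a slope of 0.611, 0.584 and 0.603 on the 3 arrays, where an undistorted ratio gives 1, and the folds below are given as measured, with no correction for this.

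The overexpressed gene itself could not be used to check the labels. The probe for SPIB was not well above background on any of the 3 arrays in either channel. Its signals were 61, 48.5 and 77 in the control channel over backgrounds of 23, 21 and 23, and 65, 56 and 99.5 in the SpiB channel over backgrounds of 40, 44 and 44, so no fold is given. Where this probe lies relative to the insert of the vector is not given in the sources used here, and the direction of every ratio rests on the dyes named in the labels. Of the 2 nearest relatives of SPIB, SPI1 was well above background on none of the arrays in either channel, and SPIC only on 1 array in the control channel.

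The comparison asked which genes change when A549 cells overexpress SpiB. The largest changes were increases. SDS, which encodes a serine dehydratase known from liver, was 125-fold higher in the SpiB cells, with a log2 ratio of 6.97 ± 0.26 (SD, n = 3) and an adjusted p of 4.43e-05. LAPTM5, a lysosomal membrane protein of haematopoietic cells, was 80.0-fold higher, at 6.32 ± 0.59. The actin-binding protein of leukocytes CORO1A was 24.6-fold higher, with nearly the same ratio on each array (4.62 ± 0.03). Of 19 tested myeloid genes, 12 rose and none fell. The decreases were smaller, the largest being that of FOXS1, a forkhead transcription factor, with a log2 ratio of -3.21 ± 0.44, which is 9.26-fold lower in the SpiB cells.

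In all, 1532 of 17074 tested genes were higher and 1771 were lower in the SpiB cells at an adjusted p under 0.05 in limma's moderated test of the mean log2 ratio, two-sided. Together these 3303 genes were 19.3% of the genes tested, and each of them had the same sign on every array that measured it. At least a 2-fold change was found for 442 of the higher and 283 of the lower genes, and at least an 8-fold change for 54 of the higher genes and for 1 of the lower, FOXS1. The counts at 2-fold were 941 and 197 with median centring and 525 and 475 with the scanner's log ratio. The share of higher genes among the calls, 46.4%, depended on how the dyes were balanced: with each array centred on its median in place of the loess curve, 7014 genes were higher and 1382 lower (83.5% higher), while the median of all genes moved to 0.23. Without replicate 1, 236 genes were higher and 193 lower, and without replicate 2, 615 and 756, in fits with 1 residual degree of freedom per gene; 758 and 634 were found with the channels fitted separately. Of the named genes, 40 of 95 passed with the same sign without replicate 1, 73 of 96 without replicate 2 and 93 of 95 without replicate 3.

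**Figure D1:**
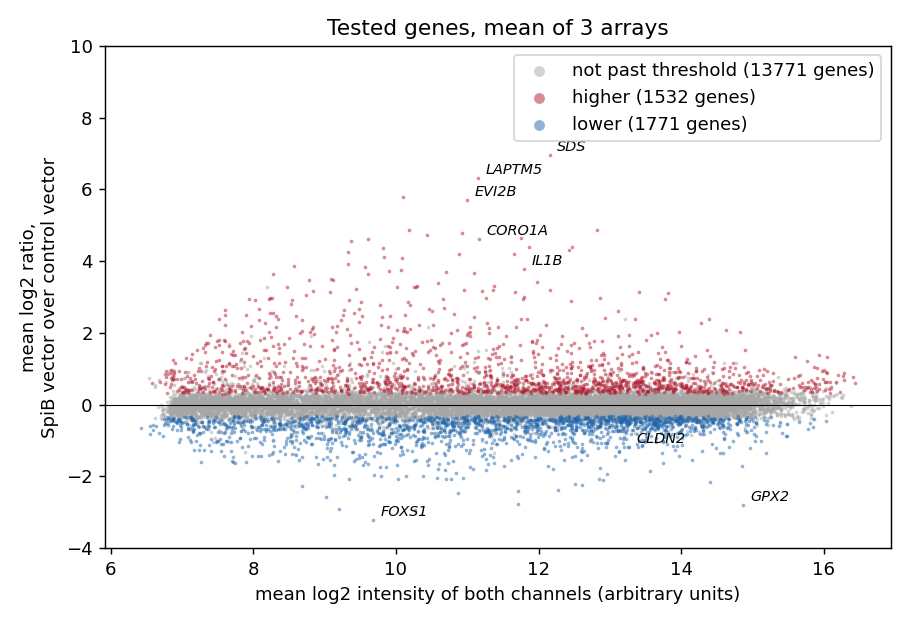
Mean log2 ratio of SpiB over control (vertical axis) against the mean log2 intensity of both channels (horizontal axis, arbitrary units) for the 17074 tested genes, each point the mean of 3 arrays. The 1532 higher genes (red) reach a log2 ratio of 6.97, while the 1771 lower genes (blue) end at -3.21.

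The other genes of the largest increases were EVI2B (log2 ratio 5.71 ± 0.41), SLA (4.88 ± 0.91), ALOX5AP (4.87 ± 0.39), PDE4DIP (4.78 ± 1.67), IDO1 (4.74 ± 2.03), TYROBP (4.64 ± 0.64) and PPBP (4.40 ± 0.68), each with n = 3 and adjusted p between 0.0002285 for EVI2B and 0.01147 for IDO1. SLA encodes an adaptor that dampens antigen receptor signalling, ALOX5AP a protein needed for leukotriene synthesis, IDO1 an enzyme that degrades tryptophan, TYROBP a signalling adaptor of myeloid and natural killer cells, and PPBP a platelet chemokine. The ratios of IDO1 and PDE4DIP were uneven: on replicate 3 they were 2.42 and 2.85, against 6.16 and 5.78 on replicate 1. Of the 3 fits that left out a replicate, IDO1 passed in 1 and PDE4DIP in 2. The other tested probes of PDE4DIP gave log2 ratios between -0.08 and 1.70, far below that of its brightest probe.

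Of the largest decreases after FOXS1, ST6GAL2 (-2.92 ± 1.18), BCAS1 (-2.90 ± 0.42), GPX2 (-2.78 ± 0.38) and NKAIN4 (-2.75 ± 0.79) came first, followed by SERPINA6 (-2.58 ± 0.25), IGF2 (-2.45 ± 1.05), NPTX1 (-2.40 ± 0.53), IGFL3 (-2.36 ± 0.46) and CRYAB (-2.26 ± 0.19), with adjusted p between 0.0007084 for CRYAB and 0.01195 for IGF2. GPX2 is a glutathione peroxidase of the gut epithelium, SERPINA6 the corticosteroid carrier of plasma, IGF2 a growth factor and CRYAB a small heat shock protein. A dimmer probe for IGF2 gave -0.36, with an adjusted p of 0.135. IGF2 passed in 1 and ST6GAL2 in 2 of the 3 fits that left out a replicate.

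**Figure D2:**
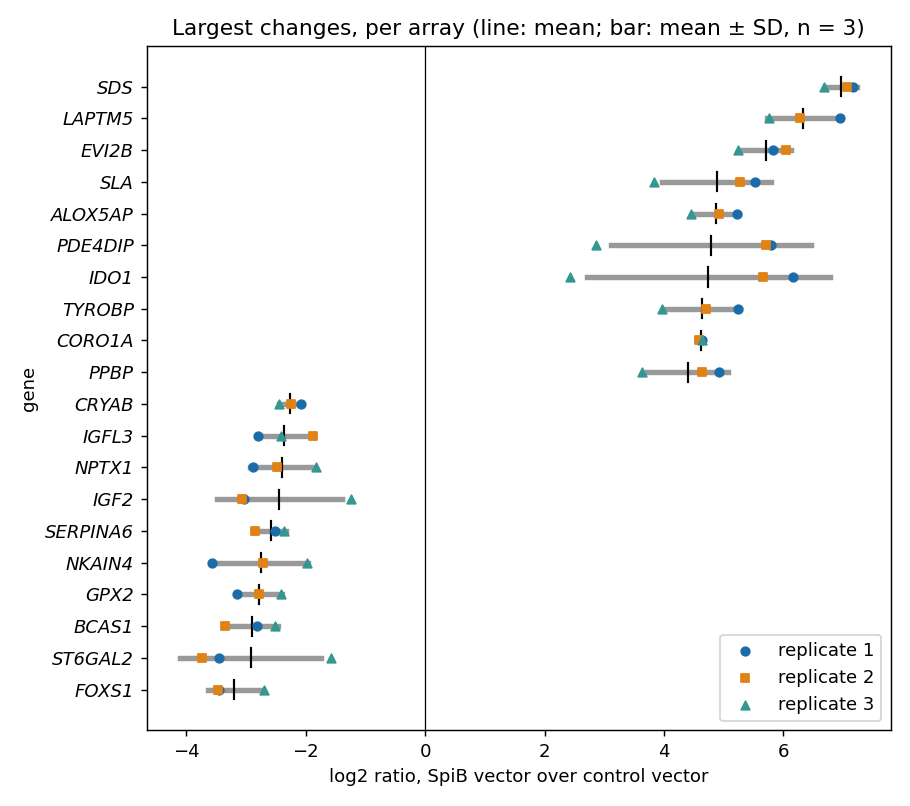
Log2 ratio of SpiB over control (horizontal axis) on each of the 3 arrays for the 10 genes with the highest and the 10 with the lowest mean among called genes measured in both channels on every array; the black line is the mean and the grey bar the mean ± SD. Replicate 3 (triangles) lies nearest to 0 for 9 of the 10 highest genes, the exception being CORO1A.

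For some genes only 1 channel was above background, and their fold is given as a nominal lower bound. It compares the mean normalized level of the bright channel with a level of the dim channel. That level is the higher of the dim probe's own level and the lowest level called above background. Where the probe's own level is the higher, the bound equals the measured fold, as for IKZF1 and TM4SF5. The bound refers to the mean of the arrays and leaves out their spread, so a single array can lie below it. It is open to dye bias. Among 68 higher genes whose control channel was above background on no array, the highest bounds were at least 13.7-fold for P2RY14, a receptor for UDP-glucose, at least 11.3-fold for CD180, a Toll-like receptor homologue of B cells, at least 9.66-fold for IKZF1, the lymphoid transcription factor Ikaros, at least 7.84-fold for TM4SF5 and at least 7.41-fold for S1PR1, a sphingosine 1-phosphate receptor. Their adjusted p lay between 0.0007162 for P2RY14 and 0.0149 for TM4SF5. On replicate 3 the log2 ratios of CD180, TM4SF5 and S1PR1 were 1.84, 1.39 and 1.58, against 4.52, 3.95 and 3.43 on replicate 1. These 3 genes did not pass without replicate 1 (adjusted p = 0.0926, 0.0978 and 0.0896), nor CD180 and TM4SF5 without replicate 2 (adjusted p = 0.0592 and 0.0742). Among 66 lower genes whose SpiB channel was above background on no array, the bounds were at least 2.59-fold lower for CDH17, an intestinal cadherin, at least 2.46-fold for the long noncoding RNA NRAD1, at least 2.25-fold for the intestinal keratin gene KRT20, at least 2.14-fold for SPOCK3 and at least 1.88-fold for VTCN1, with adjusted p between 0.002286 and 0.01305. KRT20 and SPOCK3 did not pass without replicate 1 (adjusted p = 0.0725 and 0.0812).

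Genes of myeloid cells rose as a group. Of 19 tested members of the myeloid list, 12 rose and none fell (15 and 0 adjusted over the list alone), and the median log2 ratio was 1.93, which is 3.80-fold. LAPTM5 and the tetraspanin gene CD53 (5.79 ± 0.75, adjusted p = 0.0007614) were highest. PTPRC (0.21 ± 0.28), FCER1G (0.16 ± 0.05) and MPEG1 (0.21 ± 0.26) did not pass the test. All 19 members were well above background in the control channel of at least 1 array. In a further list of transcripts abundant in leukocytes, drawn up after the data were seen, 6 of 22 tested genes rose and 1 fell, with a median of 0.56. The myeloid list stood above the other genes in camera with a preset correlation of 0.01 (adjusted p = 9.71e-12). The myeloid list did not with a correlation estimated from it, in a test on 2 residual degrees of freedom (adjusted p = 0.834 with an estimated correlation). Its median was 2.85, 2.94 and 1.32 on replicates 1, 2 and 3, and 9, 10 and 17 members rose without replicate 1, 2 and 3.

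Genes of the B cell lineage also rose, with 9 of 12 tested members higher and 1 lower (11 and 1 adjusted over the list alone), and a median log2 ratio of 0.75 (camera, adjusted p = 1.56e-05; adjusted p = 0.834 with an estimated correlation). The tyrosine kinase genes SYK (4.38 ± 1.07, adjusted p = 0.002951) and BTK (2.07 ± 0.36, adjusted p = 0.00203), which act downstream of the B cell receptor, were highest. IRF8, a transcription factor that partners with PU.1 and SpiB, fell by 0.92 ± 0.16 on the log2 scale (adjusted p = 0.004806). The list has 21 genes on the array, of which the others were too dim to test; with no filter on dim probes 9 of 21 rose and 1 fell, and the median was 0.28. Without replicate 1, 2 of the members rose and none fell. Of 10 tested members of the plasmacytoid dendritic and M cell list, 2 rose and none fell, also adjusted over the list alone, namely LILRA4 (1.07 ± 0.45) and TNFRSF11A (1.03 ± 0.13). The median of this list was -0.02 and its mean 0.17, and it did not stand apart from other genes in camera, whose direction was up (adjusted p = 0.707). Of 11 fibroblast and endothelial markers on the array, 6 were tested. PECAM1, which leukocytes and platelets express as well as endothelium, rose to 3.49 ± 1.01, and FAP fell at least 1.59-fold. These were also the 1 that rose and the 1 that fell adjusted over the list alone. With no filter on dim probes, 2 of the 11 rose and 1 fell. The median of that list was 0.02 and its mean 0.45, while camera gave it the direction down (adjusted p = 0.943).

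Inflammatory cytokine genes of the NF-kB list were higher. Of 24 tested members, 9 rose and none fell (14 and 0 adjusted over the list alone), with a median log2 ratio of 1.12 (camera, adjusted p = 8e-06; adjusted p = 0.834 with an estimated correlation). IL1B, which encodes interleukin 1 beta, was 13.8-fold higher (3.79 ± 0.39, adjusted p = 0.0005977), and the monocyte chemoattractant gene CCL2 was 8.71-fold higher (3.12 ± 0.66, adjusted p = 0.002246). Of 23 interferon-stimulated genes, 9 rose and 2 fell (11 and 2 adjusted over the list alone), with a median of 0.65 (camera, adjusted p = 0.000484; adjusted p = 0.88 with an estimated correlation). MX2 (1.96 ± 1.08, adjusted p = 0.02383) and the RNA sensor gene IFIH1 (1.72 ± 0.58, adjusted p = 0.007507) were highest, while IFI44L (-0.55 ± 0.34) was among those that fell. Both lists differed between culture pairs: the NF-kB median was 1.46, 1.75 and 0.14 on replicates 1, 2 and 3, and the interferon median 1.03, 1.39 and 0.01. With median centring 13 interferon-stimulated genes rose and none fell, with a median of 1.12, but the list did not stand above the other genes (adjusted p = 0.0789), whose median was 0.23. With median centring 18 members of the NF-kB list rose, with a median of 1.49. Members of the NF-kB list that rose numbered 2 without replicate 1, 5 without replicate 2 and 20 without replicate 3, and those of the interferon list 1, 4 and 17.

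Genes of matrix proteolysis rose in 8 of 15 cases and fell in none (8 and 0 adjusted over the list alone), with a median of 0.61 (camera, adjusted p = 0.000143; adjusted p = 0.834 with an estimated correlation). The urokinase gene PLAU was 5.24-fold higher (2.39 ± 0.08, adjusted p = 0.0004187) and MMP9, a gelatinase, 4.06-fold higher (2.02 ± 0.37, adjusted p = 0.002131). The median of the matrix proteolysis list was 0.71, 0.63 and 0.18 on replicates 1, 2 and 3. Without replicate 1, 3 of these genes rose, with a median of 0.35, and with median centring 12 rose. Of 18 genes of the unfolded protein response, 6 rose and none fell (9 and 1 adjusted over the list alone; camera, adjusted p = 0.00251; adjusted p = 0.88 with an estimated correlation), the highest being DDIT3 (1.41 ± 0.69) and CRELD2 (0.98 ± 0.51). The list median was 0.63, 0.60 and 0.08 on replicates 1, 2 and 3. None of these 18 genes rose without replicate 1 or without replicate 2, and 12 rose without replicate 3. With median centring 14 rose, with a median of 0.90. Of 23 ribosomal protein genes, 6 rose and none fell (6 and 0 adjusted over the list alone), with a median of 0.24 (camera, adjusted p = 0.000114; adjusted p = 0.834 with an estimated correlation). RPL4 was 1.93-fold higher (0.95 ± 0.05), and RPL8, measured on 2 arrays, 1.65-fold higher. Without replicate 1, 1 of them rose, and without replicate 2, 2 rose. With median centring all 23 rose, with a median of 1.11 where that of all genes was 0.23, and the scanner's log ratio gave a median of 0.14 with 3 that rose. The median of all genes is no baseline for this list, since median centring leaves in dye effects that vary with intensity. Random lists matched to these genes on intensity, with ribosomal genes left in the pool, had a median of 0.15. The central 95% of them reached up to 0.32, a range that holds the ribosomal median.

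Genes of tight junctions and of integrins and the basement membrane were lower as groups in camera at the preset correlation, but not in every setting. Claudin 2, encoded by CLDN2, forms paracellular cation pores. CLDN2 was lower in the SpiB cells on all 3 arrays, with a log2 ratio of -1.17 ± 0.23 (2.26-fold lower, adjusted p = 0.003844). Of 20 tested tight junction genes, 5 fell and 2 rose (7 and 2 adjusted over the list alone), with a median of -0.22 (camera, adjusted p = 0.0375, and 0.834 with an estimated correlation). With median centring 5 of them fell and 4 rose, with a median of -0.096. The polarity gene CRB3 fell by 0.99 ± 0.20, whereas CLDN7 (1.47 ± 0.37) and F11R (0.75 ± 0.33) rose, the latter with a second tested probe at 0.48 that did not pass (adjusted p = 0.0706). Of 21 integrin and basement membrane genes, 7 fell and 1 rose (9 and 1 adjusted over the list alone; camera, adjusted p = 0.0168; adjusted p = 0.834 with an estimated correlation), and the median of -0.21 turned to 0.12 with median centring, where the median of all genes was 0.23. ITGB6 (-1.30 ± 0.41) and NID1 (-1.03 ± 0.24) were lowest and ITGA5 rose (0.54 ± 0.18). The integrin list did not pass with median centring (adjusted p = 0.285), where 8 of its genes rose and 4 fell. Neither list passed without replicate 3 (adjusted p = 0.196 and 0.0791) or with the channels fitted separately (adjusted p = 0.0516 for both). Without replicate 1, 1 tight junction gene and 2 genes of the integrin list fell.

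**Figure D3:**
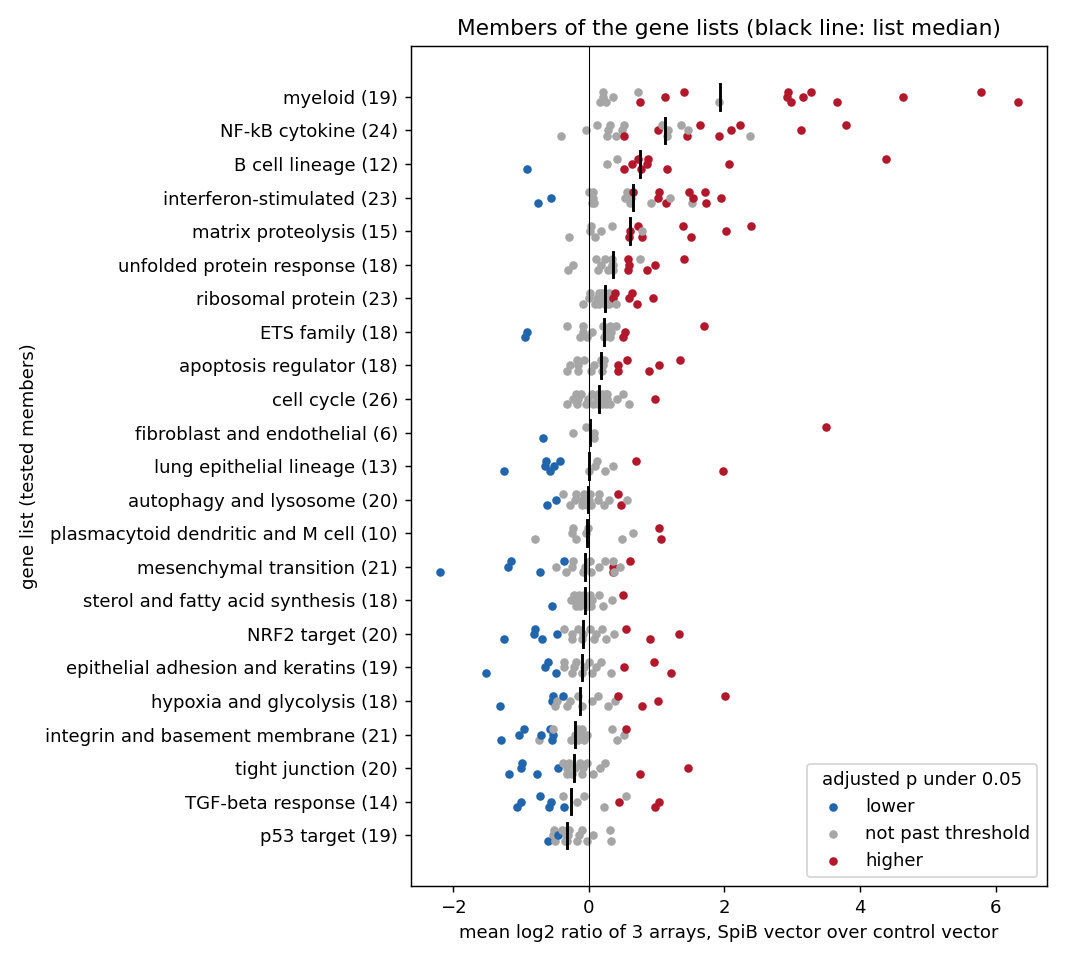
Mean log2 ratio of 3 arrays, SpiB over control (horizontal axis), of the tested members of the 23 gene lists, ordered by list median (black line); red members were higher and blue members lower at an adjusted p under 0.05, grey members were neither. The myeloid list has the highest median, 1.93. The lowest, -0.32, is that of the p53 targets, which turns to 0.10 with median centring.

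The remaining lists did not stand apart from other genes in camera. Their counts moved with the dye scaling. With median centring, where the median of all genes was 0.23, the genes that rose and fell numbered 19 and 0 for the cell cycle, 13 and 1 for autophagy, 12 and 0 for sterol synthesis, 12 and 2 for NRF2 targets and 10 and 0 for apoptosis. They numbered 9 and 5 for mesenchymal genes, 9 and 2 for the ETS family, 7 and 1 for the TGF-beta response, 7 and 1 for hypoxia, 5 and 2 for epithelial genes, and 3 and 3 for lung lineages. Without replicate 1, few members of these lists passed: none rose or fell among the epithelial, lung lineage, ETS, autophagy, sterol and p53 lists, 1 rose and none fell in the cell cycle, TGF-beta, NRF2 and apoptosis lists, 1 rose and 1 fell in the hypoxia list, and none rose and 2 fell in the mesenchymal list. Epithelial and mesenchymal genes moved both ways within each list. Of 19 epithelial adhesion and keratin genes, 3 rose and 4 fell (3 and 4 adjusted over the list alone; adjusted p = 0.691). EPCAM, an epithelial adhesion molecule, fell by 1.52 ± 0.61 and the desmosomal gene DSP by 0.64 ± 0.08. KRT8 (1.22 ± 0.61) and KRT18 (0.95 ± 0.48) rose, but a second tested probe of each did not pass (0.53 and 0.14). Of 21 mesenchymal genes, 3 rose and 5 fell (4 and 5 adjusted over the list alone; adjusted p = 0.713): TAGLN, an actin-binding protein of smooth muscle, was 4.59-fold lower (-2.20 ± 0.72) and COL1A1 2.28-fold lower (-1.19 ± 0.30), while ZEB2 (0.60 ± 0.24) and VIM (0.35 ± 0.14) rose, VIM just past the threshold (adjusted p = 0.0492) and past it under 5 of 16 alternatives, none of which left out a replicate. Of 14 genes of the TGF-beta response, 3 rose and 6 fell (4 and 7 adjusted over the list alone; adjusted p = 0.236), with TGFBR2 (1.04 ± 0.34) and TGFB1 (0.97 ± 0.09) among the former and TGFB2 (-1.05 ± 0.33) and PMEPA1 (-1.0 ± 0.47) among the latter.

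Of 13 genes of lung epithelial lineages, 2 rose and 6 fell (3 and 6 adjusted over the list alone; adjusted p = 0.685). LAMP3 (1.98 ± 1.1), which maturing dendritic cells also express, and FOXA1 (0.70 ± 0.40) rose, and the mucin gene MUC5B (-1.25 ± 0.51) and the surfactant lipid transporter gene ABCA3 (-0.65 ± 0.11) fell. The median of this list was 0.01, its mean -0.04 and camera's direction down. Of 18 genes of the ETS family, 3 rose and 2 fell (5 and 2 adjusted over the list alone; adjusted p = 0.173), with FLI1 (1.70 ± 0.53) and ELF1 (0.53 ± 0.14) higher and ELF3 (-0.93 ± 0.32) and ETS2 (-0.91 ± 0.09) lower.

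Among growth and survival genes, 1 of 26 cell cycle genes rose and none fell, both over all genes and adjusted over the list alone (adjusted p = 0.177), namely CDC20 (0.98 ± 0.31). Of 19 p53 targets none rose and 2 fell (0 and 0 adjusted over the list alone; adjusted p = 0.0913). They were BAX (-0.60 ± 0.35), whose second tested probe gave 0.10, and DDB2 (-0.45 ± 0.24), whose ratio turned to 0.10 with median centring. They passed under 9 and 8 of 16 alternatives. Of 18 apoptosis regulators, 6 rose and none fell (6 and 0 adjusted over the list alone; adjusted p = 0.0721), led by the anti-apoptotic gene BCL2A1 (1.35 ± 0.16), whose second tested probe gave 3.53, and the pro-apoptotic gene PMAIP1 (1.03 ± 0.44). These lists depended on single arrays and settings: camera called the cell cycle list higher without replicate 1 or 2 (adjusted p = 0.0463 and 0.0322) and with median centring (adjusted p = 0.0121), the p53 targets lower without replicate 1 or 2 (adjusted p = 0.0415 and 0.000796), and the apoptosis list higher without replicate 3 (adjusted p = 0.0202). The median of the cell cycle list was -0.01, -0.03 and 0.50 on replicates 1, 2 and 3, and that of the p53 targets -0.13, 0.17 and -0.81.

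Metabolic and stress lists were mixed as well. Of 20 NRF2 targets, 3 rose and 5 fell (4 and 5 adjusted over the list alone; adjusted p = 0.713), with the ferritin gene FTL (1.34 ± 0.19, and 0.58 and 0.43 in its other probes) and TALDO1 (0.90 ± 0.09) higher and the haem oxygenase gene HMOX1 (-1.25 ± 0.41) and ME1 (-0.80 ± 0.20) lower. Of 18 genes of hypoxia and glycolysis, 4 rose and 4 fell (4 and 8 adjusted over the list alone; adjusted p = 0.707). NDRG1 (2.00 ± 0.22) and VEGFA (1.02 ± 0.28) rose, ANGPTL4 (-1.31 ± 0.44) fell, and the fall of the glucose transporter gene SLC2A1 (-0.54 ± 0.21) turned to 0.03 with median centring. The median of the hypoxia list was -0.13, its mean 0.03 and camera's direction down. Of 18 genes of sterol and fatty acid synthesis, 1 rose and 1 fell, both also adjusted over the list alone (adjusted p = 0.707). The gene that fell was SQLE (-0.55 ± 0.13), which encodes squalene epoxidase. Of 20 autophagy and lysosome genes, 2 rose and 2 fell (3 and 2 adjusted over the list alone; adjusted p = 0.943), namely ATG7 (0.47 ± 0.13) and ATG3 (0.43 ± 0.12) against ULK1 (-0.61 ± 0.21) and ATG16L1 (-0.48 ± 0.09). The median of the autophagy list was -0.01, while camera's direction was up.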

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

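The tests of sign patterns, of leukocyte RNA, of dye effects and of the spike-in slope were chosen after the result was seen, and the rule that the whole bootstrap interval must lie under the lower bound was added to the leukocyte test after its median was known, which turned its outcome from excluded to open. A second leukocyte test, limited to transcripts of low control level, was also added late, after a first limit, at the highest control level of the called myeloid members, had removed 0 genes and made no test.

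Among 12161 tested probes without a gene name here, 1266 (10.4%) passed the threshold, 614 of them higher and 652 lower, a smaller share than the 19.3% of named genes; they are given here because the comparison of genes did not use them. The spike-in transcripts, which also entered no comparison of genes, had a slope of observed on expected log ratio of 0.599 on average, between 0.584 and 0.611, where an undistorted ratio gives 1. The scanner software marked this slope as in range on 0 arrays.

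The count of 3303 changed genes compares 3 culture pairs. The signs of 3 log ratios make 4 patterns, and 1 of them, the real one, gave as many calls. The highest count among the others was 0. With 4 patterns no share under 0.05 can be reached.

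The first pattern is the rise of myeloid genes, where 12 called members had a median log2 ratio of 3.07. If leukocyte RNA had entered the SpiB cultures, transcripts that leukocytes hold in abundance should rise with them. In a list of 24 such transcripts, written after 3 of them had been seen in the myeloid list, 22 were tested. Of these, 6 rose (CTSS 1.81, CD48 3.16, CXCR4 1.74, CYTIP 2.37, S100A9 2.05 and PTPN6 0.37) and 1 fell (CCR7, -0.95). Among those that did not pass, PTPRC (0.21), FCER1G (0.16), CD52 (0.17), LCP1 (0.10) and RAC2 (-0.03) were flat. S100A8 (1.92), HLA-DPB1 (1.44) and HLA-DPA1 (1.08) did not pass either, at higher ratios. The median was 0.564 with a 95% bootstrap interval over genes from 0.243 to 1.44. This interval lay below 1.53 (50% of the median of the called myeloid members) but held 0.767 (25% of it). The called members are those that rose, whereas the leukocyte list was taken whole, so a gap was partly built in. All 19 tested myeloid genes had a median of 1.93. The flat members argue against leukocytes as the whole source, while the raised ones go with it, and high control levels can hide a rise. The 14 transcripts at or below the median control level of the called myeloid members had a median of 0.908. Its interval, from 0.379 to 1.90, holds 1.53. Of these 14, 9 lay under 1.53 and 4 rose, so leukocytes as the whole source are not excluded. A dye effect stays open too, since 0 arrays had the opposite dye orientation; an action of SpiB is the explanation that the design names, and it was not tested apart from these.

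The second pattern is the near absence of the interferon shift on replicate 3. Compressed ratios on that array are argued against by its spike-in slope of 0.603, which lies between those of the other arrays. The 17 interferon-stimulated genes called higher without replicate 3 kept a median 8.77% of their log2 ratio there. Random draws of other called genes of similar ratio kept 51.4% (2.5th percentile 30.6%). NF-kB cytokine genes kept 17.8% and myeloid genes 69.5%, so the loss was uneven between lists and not particular to the interferon list. The interferon list was singled out for its low median on this array, so its small share cannot decide against a smaller response of every gene. The list medians show that not every list moved less on replicate 3. That of the p53 targets was -0.81 there against -0.13 and 0.17, and that of the cell cycle list 0.50 against -0.01 and -0.03. Neither list stood apart in camera over all 3 arrays, and the myeloid and NF-kB medians were nearer to 0 on replicate 3. A higher interferon level in control culture 3 may account for part of the interferon loss. The control channel held the 17 interferon-stimulated genes 0.467 higher there than in the other control cultures (median log2, 95% bootstrap interval over genes 0.401 to 1.05). The median ratio lost was 1.23, so this share can be neither ruled out nor taken as the whole. The 17 genes were chosen for high ratios on replicates 1 and 2, which favours low control levels on those arrays. Part of the control excess on replicate 3 may therefore be built in. Other genes chosen in the same way were not compared. The interval resampled genes, which are not independent, and does not measure the spread between cultures. The SpiB channel differed by a median of -0.589, and no biological explanation was tested.

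The third pattern is the small rise of ribosomal protein genes. Their median of 0.242 lay at the 88.4th percentile of 10000 random lists matched on intensity, whose median was 0.154. An intensity-dependent residue of the dye normalization could give such a value. The random lists were drawn with ribosomal genes left in the pool, which can bring their median nearer to that of the list. The value moved with the dye scaling, to 1.11 with median centring (all genes 0.234) and to 0.135 with the authors' value table. A dye effect of these probes cannot be told apart from a change in the cells, because 0 arrays had the opposite dye orientation.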

How the results depend on the processing

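The scaling of ratios to the same spread was the only alternative chosen after seeing the data. With median centring in place of loess, 7014 genes were higher, while DDB2 turned to 0.10 and SLC2A1 to 0.0259. The median of all genes moved to 0.23, a shift that the loess curve had removed. The shift was uneven between lists. The ribosomal median went from 0.242 to 1.11 and the autophagy median from -0.0117 to 0.565, but the myeloid median from 1.93 to 1.9. The value of 0.23 is therefore no baseline for a single list or gene. With the channels fitted separately and no replicate block for the pairing of cultures on an array, 758 genes were higher and 634 lower, of which 757 and 634 were also called with the pairing. Requiring at least a 2-fold change left 442 and 283; these became 941 and 197 with median centring, 525 and 475 with the scanner's log ratio, 527 and 473 with the authors' value table, and 214 and 171 without replicate 1. Leaving out 1 replicate gave 236 to 2243 higher and 193 to 2171 lower genes, the lowest without replicate 1 and the highest without replicate 3; these fits have 1 residual degree of freedom. The counts with no minimum change stayed within 1.5 times under all other alternatives. Of 96 named genes that were tested, those that passed with the same sign numbered 86 with median centring, 74 with separate channels, 89 with the scanner's log ratio, 90 with the authors' value table, 40 of 95 without replicate 1, 73 of 96 without replicate 2 and 93 of 95 without replicate 3. All 9 calls of lists were lost with an estimated correlation. That setting tests on 2 residual degrees of freedom, so the loss does not show that correlation between genes made the calls. The tight junction list lost its call at an estimated correlation of -0.0284, below the preset 0.01 (camera, unadjusted p = 0.0147 and 0.117). The B cell list lost its call at 0.0139. Other estimates were higher, such as 0.549 for the myeloid list. Fry, which tests a list against no change rather than against other genes, called none of the 9 (adjusted p from 0.0546 to 0.361). The interferon and integrin lists also lost theirs with median centring (adjusted p = 0.0789 and 0.285). The cell cycle list passed with median centring (adjusted p = 0.0121) and without replicate 1 or 2 (0.0463 and 0.0322), the p53 list without replicate 1 or 2 (0.0415 and 0.000796), and the apoptosis list with separate channels, the mean of probes and without replicate 3 (0.0469, 0.0139 and 0.0202); the cause was not tested. For SPIB no alternative gives an interpretable ratio, because neither channel was above background; with no filter on dim probes its signals gave 0.01 ± 0.08 (SD) on the log2 scale (adjusted p = 0.943). Aquantile normalization leaves log ratios unchanged by construction. Signal over background limits the dim probes, whose ratios the offset shrinks.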

Other observations

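The hypotheses here were formed from the largest changes, and each test was set before its own result was seen. The genes named in this part were chosen after their values were seen.

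Genes that rose at least 2-fold often lay next to each other. Of 442 such genes, 47 pairs were direct neighbours in the order of tested genes on a chromosome, against a median of 11 in 10000 random gene sets of the same size, whose central 95% reached up to 18 (permutation p = 1e-04, the smallest these can give). The pairs included the adaptor genes HCST (log2 ratio 1.99) and TYROBP (4.64), the interleukin genes IL1A (2.23) and IL1B (3.79), the chemokine genes CCL2 (3.12) and CCL7 (2.91), the integrin genes ITGAM (3.66) and ITGAX (2.21), and the complement regulators C4BPB (2.14), C4BPA (4.38) and CD55 (2.28). The 283 genes that fell at least 2-fold made 30 such pairs, against a median of 5. The excess was thus not particular to the genes that rose. The random sets were drawn from all tested genes and were not matched on intensity. Shared regulation of neighbours is a candidate explanation of the 47 pairs. Leukocyte RNA, left open above, could also raise neighbouring leukocyte genes together, such as ITGAM and ITGAX. Cross-hybridisation between related neighbours and transcripts that run from one gene into the next were not tested.

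A wider set of leukocyte genes rose in part. Of 26 tested genes in a list of 30 leukocyte signalling and receptor genes outside the fixed lists, 9 rose and 2 fell, against a median of 2 higher genes in random lists matched on intensity, whose central 95% reached up to 6. Adjusted over the list alone, 11 rose and 2 fell. The integrin gene ITGAX (2.21 ± 1.13, n = 3), the Toll-like receptor gene TLR4 (2.23 ± 0.46) and the myosin gene MYO1F (1.99 ± 0.42) rose, NCKAP1L was at least 4.38-fold and ARHGAP9 at least 3.43-fold higher, and DOCK2 was 2.30-fold lower (-1.20 ± 0.30). VAV1 (0.16), WAS (0.04), ITGAL (-0.08), SELPLG (0.13) and SPN (-0.01) did not pass. The 9 calls fit the hypothesis that SpiB may raise a part of the leukocyte programme in these epithelial cells. A dye effect stays open for these genes. A leukocyte source is not excluded either: the flat members argue against it as the whole cause, while the raised ones go with it.

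A list of hepatic and intestinal genes held more lower members than random lists, but many of its members did not change. In a list of 30 such genes that left out those already seen among the largest decreases, 24 were tested, 7 fell and 1 rose, against a median of 2 lower genes in matched random lists, whose central 95% reached up to 6. Adjusted over the list alone, 10 fell and 3 rose. UGT2B7 (-1.47 ± 0.18), APOH (-1.44 ± 0.87), NR5A2 (-0.70 ± 0.21) and the 3 fibrinogen genes FGA (-0.83 ± 0.13), FGB (-1.57 ± 0.30) and FGG (-1.11 ± 0.35) fell, and TTR was at least 1.26-fold lower. AGR2 (0.94 ± 0.58) rose. Among the intestinal genes, CDX2 (-0.19), LGALS4 (-0.17), TFF3 (-0.17) and CEACAM6 (0.63) did not pass. Nor did the hepatic genes HNF4A (0.04), APOA1 (0.04), HP (-0.01) and ALB (-0.28), so neither lineage fell as a whole. The fibrinogen genes are neighbours and may not count as 3 independent genes, and the 7 calls lie only just above the random range. No dye swap bears on them.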
